A study of Mus musculus with 3 samples.

How the data were processed

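Messenger RNA abundance was measured by RNA sequencing in left ventricles of C57BL6J mice of 3 genotypes. Per the labels, RNA of 3 mice was pooled for each genotype and sequenced on an Illumina instrument, which gives 3 libraries and 1 library per genotype. Egln1_floxed is the control pool, Egln1_Tie2Cre carries Cre recombinase under the Tie2 promoter to delete Egln1, and Egln1_Hif2a_Tie2Cre is labelled as deleted for both Egln1 and Hif2a. The Tie2 promoter is active in endothelial cells and also in blood-forming cells.

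The authors deposited 3 tables, each comparing a pair of libraries. Per the submitters' processing notes, reads were handled with TopHat2, a spliced-read aligner, and Cuffdiff, which estimates and compares transcript abundance. The versions of both, the genome build and the annotation release are not given in the sources used here. Per the file headers, the deposited values are FPKM (fragment numbers scaled by transcript length and by the total of mapped fragments) for each library, with a q-value per gene from the authors' own test. That q-value compares 2 pooled libraries, not 2 genotypes, since no genotype has a second library. Each column was assigned to its library by the sample titles in the table's name, and the assignment was checked on values that recur between tables. The floxed library had identical FPKM in its 2 tables for 14368 of 14369 shared genes, with a largest relative difference of 0.00088. The Egln1_Tie2Cre library matched for 14489 of 14489 genes and the Egln1_Hif2a_Tie2Cre library for 14367 of 14367.

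The tables list 14827 genes for Egln1_Tie2Cre against Egln1_floxed, 14894 for Egln1_Hif2a_Tie2Cre against Egln1_Tie2Cre and 14843 for Egln1_Hif2a_Tie2Cre against Egln1_floxed. They cover 15503 genes together, of which 14164 occur in all 3. The number of genes with an FPKM of 0 in either library was 0 in each table, and no ratio is given for a gene at 0. Of the genes not in all 3 tables, 733 occur in 2 tables, which gives them a positive FPKM in every library, and 606 in only 1 table. Absence from a table thus does not by itself mean that a gene was undetected, and its reason is not given. Read counts and sequencing depth are unknown, because FPKM values do not keep them, and no interval that needs counts is given for an FPKM.

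The log2 ratio of FPKM + 1 was computed for each pair of libraries, which understates the difference of genes at low FPKM. Folds printed beside FPKM values are plain ratios of FPKM. Genes with a mean FPKM of at least 1 over the pair were kept, leaving 11978, 11999 and 11888 genes in the order above. Genes at least 2-fold apart were counted in each direction. With 1 library per genotype no difference has a replicate check, and no p-value or standard error was computed.

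For each of 36 gene lists, the median log2 ratio of the measured members was set against 10000 random lists of the same size, matched on mean expression in 20 bins. A list was said to stand apart at a percentile of 2.5 or less or of 97.5 or more, which describes these libraries only. Lists with fewer than 3 measured members were given no percentile. The lists cover targeted genes and HIF pathway members, glycolytic HIF targets, angiogenic, fetal stress, contractile, collagen and matricellular genes. They also cover endothelial, arterial, venous, smooth muscle, fibroblast, macrophage, lymphocyte, neutrophil, erythroid and platelet markers. Further lists hold cytokine, interferon, antigen presentation, proliferation, fatty acid, oxidative phosphorylation, mitochondrially encoded, ribosomal, unfolded protein, immediate early, clock and iron genes. The last lists hold atrial, conduction, epicardial, adipocyte, other-tissue, Schwann cell and sex-linked genes.

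The position of the Egln1_Hif2a_Tie2Cre library was computed for genes at least 2-fold apart between the other libraries, as 0 at the floxed value and 1 at the Egln1_Tie2Cre value. Shares of genes nearer the floxed value carry exact Clopper-Pearson 95% intervals, which treat genes as independent and cover counting error only. The share that noise alone would give was computed from the spread of each library among genes without a copy, taken as normal noise, after the results were seen. That spread cannot be separated from genotype changes with 1 library each. Genes were named by a fixed rule that gave 280 genes. It takes all members of the targeted list and the 10 genes with the largest log2 ratio in each direction and comparison, at an FPKM of at least 5 in the higher library, without predicted, unnamed or sex-linked genes. It also takes up to 4 members of each list that stands apart or answers the study's question, and up to 2 of each other list. Some genes that the rule names are not reported here. The comparisons, gene lists, thresholds, naming rule and a first set of alternatives were fixed before the data were examined. Those alternatives are a pseudocount of 0.1, no filter, a mean FPKM of at least 5, a threshold of 1.5-fold, median centring, rescaling without the 20 most abundant genes, values from the other table, and the authors' q-value of at most 0.05 with the 2-fold threshold.

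The division of genes by near-identical copies was added after seeing the data, as was a second ranking of named genes within the coding genes that have no copy. Gene identifiers of 15299 genes were matched to GENCODE mouse release M21, whose assembly GRCm38 gives the coordinates printed here. Transcripts were searched against each other with BLAST 2.17.0, and a gene was said to have a copy where another gene shared a stretch of at least 100 bases at 95% identity or more. Genes were classed as pseudogenes, coding genes with a copy, coding genes without a copy, mitochondrial genes, or genes not searched (noncoding, unmatched or without a transcript sequence). In the centred version of the copy-free set, the median log2 ratio of each of 5 length classes by 4 exon-number classes was subtracted.

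The method was tested on simulated data for Egln1_Tie2Cre against Egln1_floxed with 11751 genes and a noise SD of 0.2 on the log2 scale per library. It recovered 189 of 196 genes changed 4-fold (96.4%) and called 0 of 11555 unchanged genes. That noise gives ratios an SD of 0.283, narrower than the robust SD of 0.393 measured over all genes. With noise as wide as measured, it recovered 188 of 196 changed genes (95.9%) and called 47 of 11530 unchanged genes. At the narrower noise, of 200 simulated unchanged lists of 25 genes, 13 stood apart, and 50 of 50 lists shifted by 0.4 on the log2 scale did. The simulated genes varied independently of each other, which members of a real list need not do. These shares are therefore not error rates of the real lists. Of 34, 35 and 35 real lists with a percentile, 8, 11 and 9 stood apart higher in the order of comparisons given above. On the lower side 7, 7 and 6 did. Computation used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1. Handwritten annotation columns in one deposited table hold no measurements and were not used here.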

Results

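Left ventricular RNA from 3 genotypes of mouse was compared, with 1 pooled library of 3 mice per genotype. The study's title concerns loss of endothelial PHD2, the oxygen-sensing enzyme encoded by Egln1 that marks hypoxia-inducible factors (HIF) for degradation, and hypertrophy and fibrosis of the heart. The first comparison asks what differs in the ventricle when Egln1 is deleted with Tie2Cre, and the other comparisons ask the same when Hif2a is deleted as well. Hif2a is the protein encoded by Epas1. Values are FPKM from single pools, so no difference given here has a replicate check, and the depth is unknown.

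The targeted genes were read first. Egln1 (GRCm38 chromosome 8, 124908587 to 124949324, minus strand) had an FPKM of 129.5 in the floxed library, 95.7 in the Egln1_Tie2Cre library and 129.0 in the library labelled Egln1_Hif2a_Tie2Cre. Epas1 (chromosome 17, 86753700 to 86833410, plus strand) had 77.4, 65.0 and 54.5 in the same order. Egln1 was thus 1.35-fold lower in the Egln1_Tie2Cre library and within 1.004-fold of the control in the library labelled Egln1_Hif2a_Tie2Cre. The latter goes against the Egln1 part of that label. Epas1 was 1.42-fold lower than floxed in that library, the direction its label gives, but also 1.19-fold lower in Egln1_Tie2Cre. Gene-level FPKM of whole ventricle is a weak check of a deletion in endothelial cells, since cardiomyocytes keep the gene and the transcript of a deleted allele can still be counted outside the removed exons. Directions involving this library rest on its label. Hif1a, which encodes the other main HIF alpha subunit and overlaps another coding gene, was 19.3, 20.1 and 15.0. Arnt, the HIF beta subunit, was 17.6, 18.4 and 14.2, and Vhl, the ubiquitin ligase subunit that recognises hydroxylated HIF, was 4.27, 3.68 and 3.65. Egln2, a paralogue of Egln1 that overlaps another coding gene, was 27.5, 24.97 and 25.9. Tek, the endothelial receptor whose promoter drives Tie2Cre, was 16.5, 23.6 and 17.5. Egln3, another HIF prolyl hydroxylase and itself a HIF target, was 25.2, 19.9 and 65.3. The list medians of targeted genes and HIF pathway members were -0.15, -0.13 and -0.13 for Egln1_Tie2Cre over floxed, Egln1_Hif2a_Tie2Cre over Egln1_Tie2Cre and Egln1_Hif2a_Tie2Cre over floxed, at percentiles 6.22, 32.8 and 8.12. The first of these stood apart against random lists of genes without a copy (percentile 2.06), with the same 8 measured members and the same median. It did not after centring by length and exon number (percentile 13.81).

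**Figure D1:**
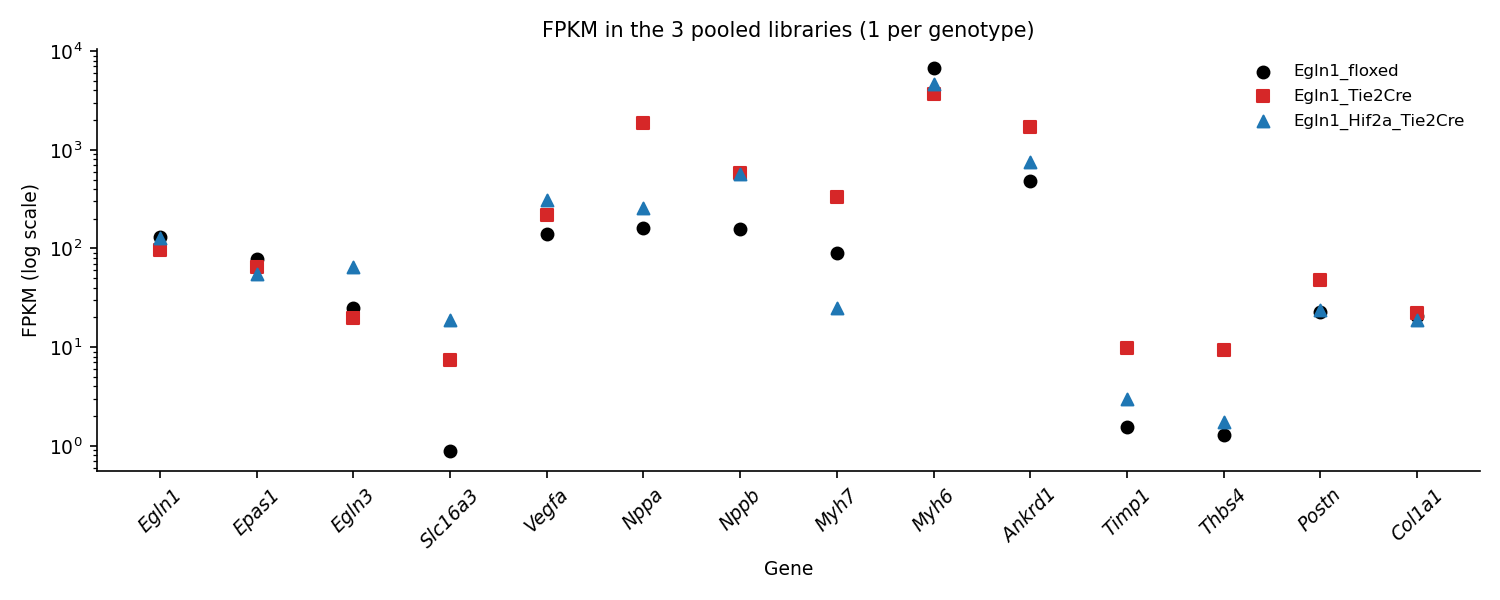
FPKM on a log axis of 14 genes in the 3 pooled libraries, 1 point per library with no error because each genotype has 1 pool. Nppa stands at 1858 in the Egln1_Tie2Cre library against 160.2 in the floxed library, while Slc16a3 is highest in the library labelled Egln1_Hif2a_Tie2Cre at 18.7.

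In the Egln1_Tie2Cre library, cardiac stress genes were higher than in the floxed library. Nppa, which encodes atrial natriuretic peptide, was 1858 against 160.2 FPKM (11.6-fold). Nppb, which encodes B-type natriuretic peptide, was 576 against 157 (3.68-fold), and Ankrd1, a stress-responsive titin-associated protein, was 1688 against 485 (3.48-fold). Myh7, the slow myosin heavy chain of the fetal mouse ventricle, was 330.4 against 89.95 (3.67-fold), though it overlaps another gene and is uncertain. Of the 23 measured fetal and hypertrophic stress genes, 13 were at least 1.5-fold higher, 5 of them at least 2-fold, and 0 were 1.5-fold lower. The list median was 0.72 (percentile 100), and 0.57 (percentile 100) among members without a copy after centring by length and exon number. Acta1, the skeletal alpha-actin re-expressed in stressed ventricle, was 719.5 against 288 but overlaps another gene. Nppa and Nppb lie beside each other on chromosome 4, at 148000722 to 148002079 and 147985788 to 147987205. Atrial markers were higher in the same library, with a list median of 1.01 (percentile 100) and 6 of 11 measured members at least 2-fold higher. These included Myl7, an atrial myosin light chain (74.0 against 26.3), Myl4, another atrial light chain (43.5 against 20.1), and Dkk3, a secreted glycoprotein (9.07 against 2.65).

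Adult contractile and calcium-handling genes went both ways. Of 31 measured members, 3 were at least 1.5-fold higher and 3 at least 1.5-fold lower, and the list median was 0.00 (percentile 6.16). Myh6, the fast adult myosin heavy chain, was 3645 against 6691 FPKM (1.84-fold lower). Kcnd2, a potassium channel of the transient outward current, was 1.53 against 5.88, and Hrc, a calcium-binding protein of the sarcoplasmic reticulum, was 257 against 473. Csrp3, a Z-disc protein, was 2131 against 1159. The list median among members without a copy after centring was -0.085 (percentile 1.03), so the call depends on that setting.

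Matricellular and profibrotic genes were higher in the Egln1_Tie2Cre library, whereas the collagen list was not. Of 34 measured matricellular members, 15 were at least 1.5-fold higher, 11 at least 2-fold, and 0 at least 1.5-fold lower, with a median of 0.34 (percentile 99.98). Thbs4, a thrombospondin of stressed muscle, was 9.44 against 1.27 FPKM (7.42-fold). Comp, a cartilage matrix protein, was 10.04 against 1.80 (5.59-fold), and Cilp, a matrix protein that binds transforming growth factor beta, was 11.9 against 3.37 (3.52-fold). Timp1, an inhibitor of matrix metalloproteinases, was 9.81 against 1.53 but overlaps another coding gene. Among 27 measured collagen and collagen-processing genes, 4 were at least 1.5-fold higher and 2 lower, and the median was -0.01 (percentile 27.3). Pcolce2, which enhances procollagen cleavage, was 15.2 against 6.51, and Lox, the collagen cross-linking enzyme, was 2.49 against 1.28. Serpinh1, the collagen chaperone, was lower at 59.6 against 98.9. Fibroblast markers had a median of -0.14 (percentile 3.46). The call depends on the setting, since the same 19 members and median lay at percentile 0.71 against random lists of genes without a copy. After centring by length and exon number the median was 0.045 (percentile 57.76). Mgp, a calcification inhibitor of the matrix, was higher at 511.7 against 230.3, and Smoc2, a matrix glycoprotein, was lower at 19.5 against 35.5. Epicardial and mesothelial markers were higher in the same library (1.78, percentile 99.99, 5 members), a call that ended among genes with a mean FPKM of at least 5 (percentile 96.97).

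Glycolytic and metabolic HIF targets divided by whether the gene has a near-identical copy elsewhere in the genome. Over all 31 measured members the median was 0.15 (percentile 78.3), with 6 at least 1.5-fold higher and 7 at least 1.5-fold lower. Among the 20 members without a copy, 6 were at least 1.5-fold higher and 0 lower, with a median of 0.33 (percentile 99.28), and 0.26 (percentile 99.63) after centring by length and exon number. Slc16a3, which exports lactate, was 7.43 against 0.876 FPKM (8.48-fold; chromosome 11, 120948480 to 120960868). The lowest members all have copies and are therefore uncertain. Gapdh, a glycolytic enzyme, was 4.98 against 2058, Pgk1, phosphoglycerate kinase, was 31.6 against 247, and Eno1, enolase, was 26.6 against 141. Angiogenic and vasoactive genes had a median of 0.06 (percentile 72.0) over 28 measured members, with 6 at least 1.5-fold higher and 3 lower. Calcrl, the receptor component for adrenomedullin, was 27.2 against 8.51. Aplnr, the apelin receptor, was 3.77 against 18.1, and its ligand gene Apln was 2.35 against 7.34. Among genes with a mean FPKM of at least 5, the angiogenic list stood apart (0.29, percentile 97.69).

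Endothelial markers had a median of 0.08 (percentile 39.6) over 30 members, 5 at least 1.5-fold higher and 3 lower. Vwf, the clotting factor carrier stored in endothelium, was 89.2 against 20.4 FPKM (4.37-fold), and Icam2, an endothelial adhesion molecule, was 39.5 against 19.96. Aqp1, a water channel of microvascular endothelium, was 49.4 against 179 (3.62-fold lower). Arterial and Notch genes had a median of 0.08 (percentile 78.9), with Hey1, a Notch target, at 12.3 against 5.54. Venous and lymphatic genes had a median of 0.05 (percentile 66.7), with Prox1, the lymphatic regulator, at 6.26 against 9.33. Smooth muscle and pericyte markers were lower, with a median of -0.23 (percentile 0.33) and 14 of 20 members below the control. Rgs4, a G-protein regulator of pericytes, was 4.21 against 7.28, and Kcnj8, a potassium channel of pericytes, was 15.5 against 24.3. Mcam, an adhesion molecule of the same list, was higher at 34.8 against 18.4. Macrophage and monocyte markers had a median of -0.27 (percentile 0.66), which did not stand apart among members without a copy (-0.17, percentile 3.72) and did so again after centring these (-0.28, percentile 0.35). Folr2, a marker of resident macrophages, was 3.72 against 9.27, and Lgals3, the galectin of activated macrophages, was 4.27 against 1.46.

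Across all 11978 genes kept, 471 were at least 2-fold higher and 460 at least 2-fold lower in the Egln1_Tie2Cre library, and these calls divided by gene class. Of 260 pseudogenes, 192 were at least 2-fold higher and 16 lower, with a median log2 ratio of 3.46. Of 1677 coding genes with a copy, 36 were higher and 334 lower (median -0.19). Of 9488 coding genes without a copy, 185 were higher and 78 lower (median 0.04), and the 542 genes not searched gave 58 higher and 29 lower. The 10 genes with the largest positive ratios were 9 pseudogenes and 1 gene not searched, Rps10-ps2, which is a pseudogene by its symbol. Fabp3-ps1, a processed copy of the fatty acid binding protein gene, was 2449 against 2.27 FPKM, while its parent Fabp3 was 315 against 4115. The 10 genes with the largest negative ratios were 8 coding genes with a copy and 2 mitochondrial genes. Rps29, a protein of the small ribosomal subunit, was 2.20 against 954, and mt-Co2, a subunit of cytochrome oxidase, was 29.96 against 51970. Ribosomal protein genes had a list median of -3.55 (percentile 0), with 34 of the 35 measured members having a copy. All of these values are uncertain as expression levels, because a read from near-identical sequences can be assigned to more than 1 gene.

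**Figure D2:**
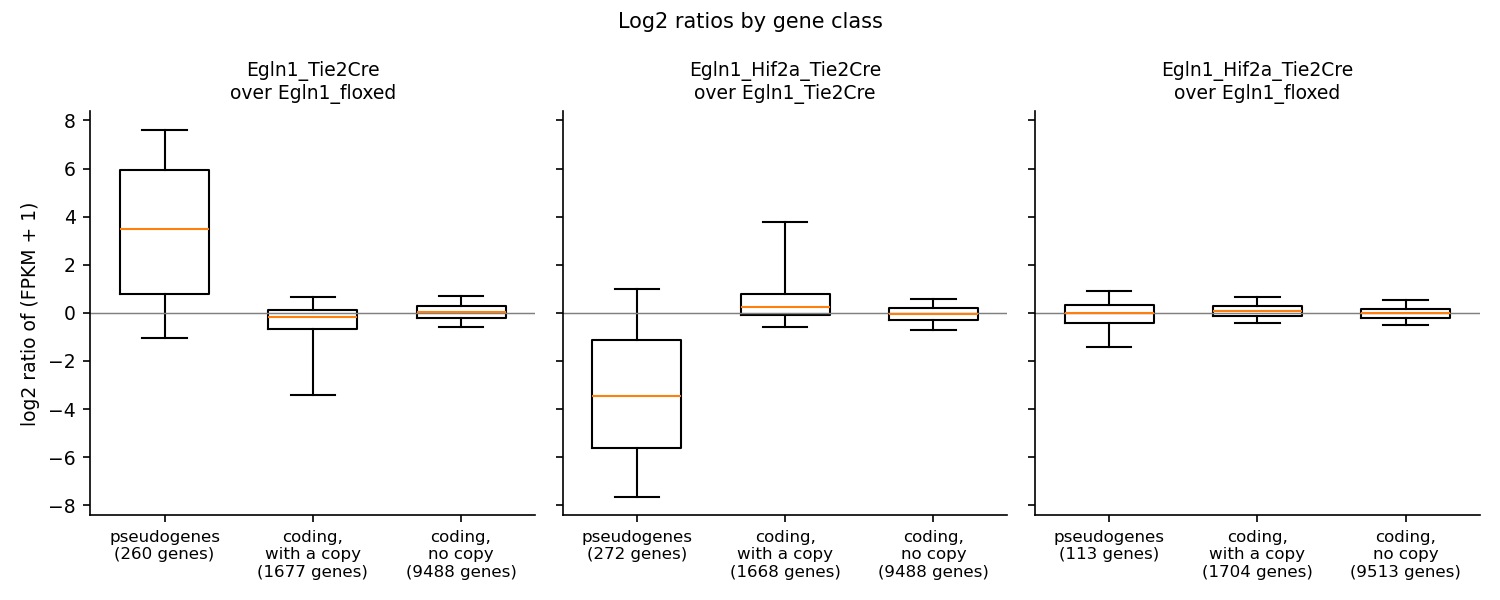
Log2 ratios of FPKM + 1 for pseudogenes, coding genes with a copy and coding genes without a copy in each comparison, as boxes of the quartiles with the median and whiskers at percentiles 5 and 95. The boxes also hold genes not listed for a comparison whose values in both libraries come from the other deposited comparisons. Over the genes listed for each comparison, the pseudogene median is 3.46 for Egln1_Tie2Cre over floxed, -3.46 for Egln1_Hif2a_Tie2Cre over Egln1_Tie2Cre and 0.00 for Egln1_Hif2a_Tie2Cre over floxed.

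Within the coding genes without a copy, the second ranking named further genes. S100a8 and S100a9, calcium-binding proteins abundant in neutrophils, were 22.7 against 0.489 and 31.9 against 1.47 FPKM. Krt19, an epithelial keratin also found in mesothelium, was 13.7 against 0.219. Syn3, Serinc4, Fam221b, Map3k15 and Tnfrsf9 also ranked among the highest, but each overlaps another coding gene and is uncertain. At the low end, Mylk4, a myosin light chain kinase family member, was 18.0 against 68.8, and Rsad2, an antiviral interferon-induced enzyme, was 1.98 against 10.2. Retnla, a secreted product of alternatively activated macrophages, was 0.697 against 6.48, and Hbb-bt, an adult beta-globin, was 8.45 against 52.2. In the authors' deposited table, which compares 2 libraries and not 2 genotypes, 8 genes were higher and 61 lower at a q-value of at most 0.05. By gene class, 58 of the lower genes were coding genes with a copy and 3 of the higher genes were pseudogenes. The authors' deposited table placed 7 coding genes without a copy past that threshold. They were Nppa (q = 0.0112), Myot, a Z-disc protein (5.28-fold, q = 0.0112), Nppb (q = 0.0210), Bdh1, a ketone body enzyme (4.37-fold, q = 0.0387), and Ptgds, a prostaglandin D synthase (3.10-fold, q = 0.0387), all higher, and Mylk4 and Aqp1 (both q = 0.0112), lower.

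**Figure D3:**
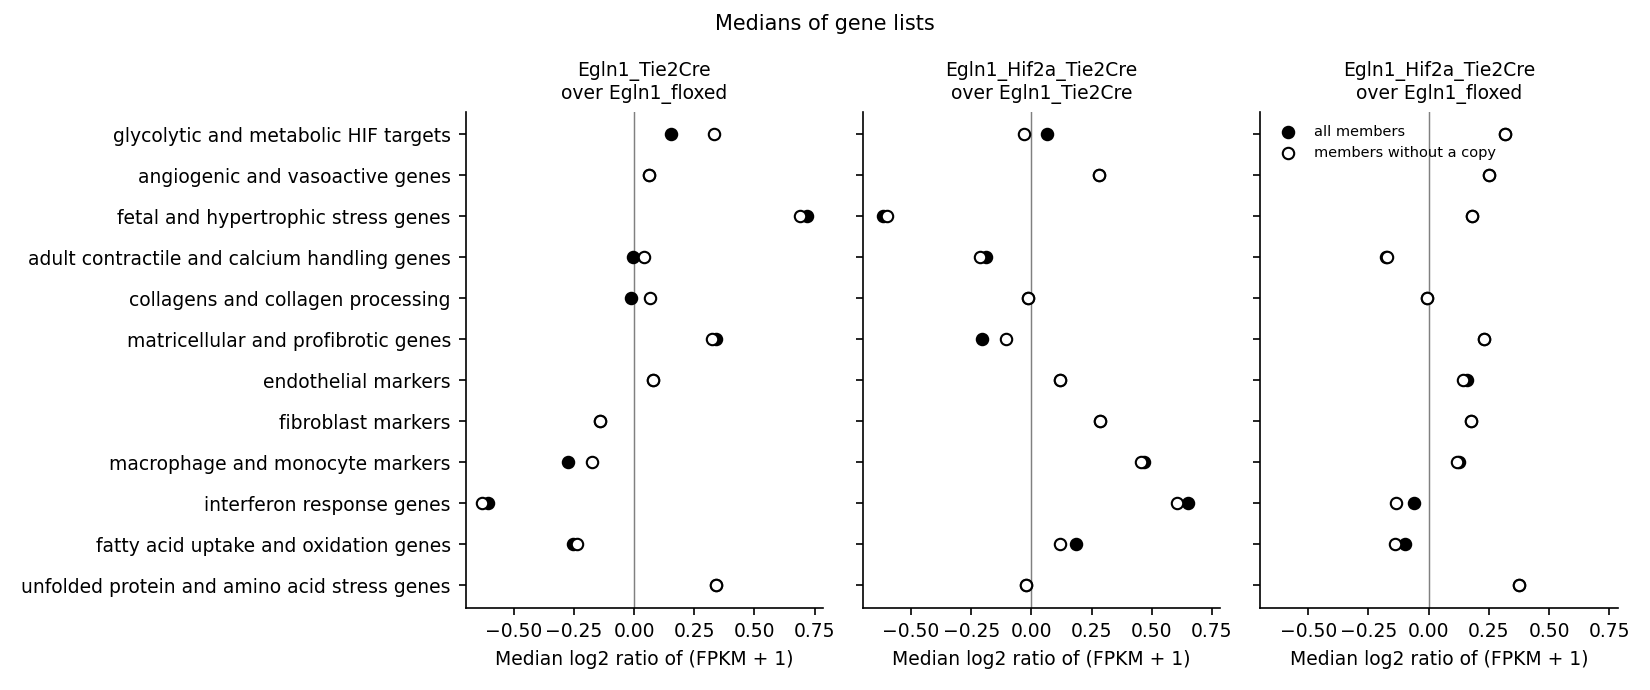
Median log2 ratio of FPKM + 1 for 12 gene lists in each comparison, with filled circles for all measured members and open circles for members without a copy. The fetal and hypertrophic stress list has a median of 0.72 for Egln1_Tie2Cre over floxed and -0.62 for Egln1_Hif2a_Tie2Cre over Egln1_Tie2Cre.

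In the library labelled Egln1_Hif2a_Tie2Cre, HIF target and angiogenic genes were higher than in the floxed library. Of 31 glycolytic and metabolic HIF targets, 25 were above the control and 6 at least 1.5-fold higher, with 0 at least 1.5-fold lower and a median of 0.32 (percentile 99.95). Slc16a3 was 18.7 against 0.876 FPKM (21.4-fold), Egln3 was 65.3 against 25.2 (2.60-fold), and P4ha1, a collagen prolyl hydroxylase, was 36.3 against 16.3 (2.23-fold). Of 29 angiogenic and vasoactive genes, 23 were above the control, with a median of 0.25 (percentile 100), but 6 were at least 1.5-fold higher and 1 at least 2-fold. Vegfa, the main endothelial growth factor, was 311 against 142 (2.20-fold), and Apold1, an endothelial early response gene, was 7.95 against 4.13. Fgf2, a fibroblast growth factor, had the largest ratio of the list and was lower at 1.03 against 4.65 (4.53-fold), though it overlaps another coding gene and is uncertain. Egln1 itself did not differ between these libraries, as given above.

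Stress genes went both ways in the same comparison. Nppb was 568 against 157 FPKM (3.63-fold higher), close to its value of 576 in the Egln1_Tie2Cre library, while Nppa was 256 against 160.2 (1.60-fold). Myh7 was lower, at 25.04 against 89.95, and Myh7b, a related myosin heavy chain, was 85.1 against 36.2, both overlapping other genes. The list median of the fetal and hypertrophic stress genes was 0.18 (percentile 87.1), and 0.15 (percentile 97.59) among members without a copy after centring. Adult contractile and calcium-handling genes were lower, with a median of -0.18 (percentile 0) and 19 of 32 members below the control. Ryr2, the calcium release channel, was 85.8 against 145, and Kcnj11, a subunit of the ATP-sensitive potassium channel, was 23.9 against 43.6.

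Matricellular and profibrotic genes had a median of 0.23 (percentile 99.97), with 7 of 34 at least 1.5-fold higher and 0 lower. Meox1, a transcription factor of activated fibroblasts, was 11.7 against 5.40 FPKM, and Sfrp2, a secreted Wnt modulator, was 2.64 against 1.11. The list no longer stood apart among genes with a mean FPKM of at least 5 (0.15, percentile 94.55). Collagen genes had a median of -0.01 (percentile 44.3), with 0 of 27 at least 1.5-fold higher or lower. Serpinh1 was 143 against 98.9, and Col15a1, a basement membrane collagen, was 39.0 against 29.1.

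Endothelial markers had a median of 0.16 (percentile 94.4), with Emcn, a sialomucin of capillaries and veins, at 44.8 against 21.4 FPKM, and Cldn5, a tight junction protein, at 24.3 against 14.4. Arterial and Notch genes stood apart at 0.21 (percentile 99.67), with Nrarp, a Notch feedback regulator, at 8.63 against 5.43. Venous and lymphatic genes had a median of 0.28 (percentile 99.57), which lay inside the random range among genes with a mean FPKM of at least 5 (percentile 86.03). Their example Lyve1, a lymphatic hyaluronan receptor, was 11.7 against 8.98. Smooth muscle and pericyte markers had a median of 0.07 (percentile 68.4), with Higd1b, a pericyte gene, at 24.4 against 11.9. Fibroblast markers had 0.17 (percentile 94.9, and 97.84 among members without a copy after centring), with Dpt, dermatopontin, at 71.4 against 48.4. Macrophage markers had 0.13 (percentile 95.3, and 98.08 among genes with a mean FPKM of at least 5), with Tyrobp, a myeloid signalling adaptor, at 28.2 against 14.0.

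Of 11888 genes kept, 64 were at least 2-fold higher and 52 lower in the library labelled Egln1_Hif2a_Tie2Cre than in the floxed library. After rescaling without the 20 most abundant genes the split was 41 higher and 106 lower, since this scaling moved the median of all genes by -0.17 on the log2 scale. Pseudogenes gave 6 higher and 8 lower of 113, and coding genes with a copy 7 higher and 5 lower of 1704. Among coding genes without a copy, 35 were higher and 30 lower. Beyond the genes above, Pygl, liver glycogen phosphorylase, was 6.58 against 1.74 FPKM, Ccl6, a myeloid chemokine, was 23.4 against 7.90, and Tnfrsf12a, the receptor of the cytokine TWEAK, was 73.9 against 28.4. Pttg1, securin, was 12.6 against 97.4 (7.76-fold lower), and Wee1, a kinase that restrains mitotic entry, was 3.58 against 10.1. The authors' deposited table held 1 higher gene, Nppb (q = 0.0210), and 1 lower gene, Cyfip2, a regulator of actin nucleation that overlaps another gene (7.68-fold, q = 0.0112).

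Between the library labelled Egln1_Hif2a_Tie2Cre and the Egln1_Tie2Cre library, stress genes were lower in the former. The comparison of Egln1_Tie2Cre with floxed uses the same single Egln1_Tie2Cre pool. A deviation of that pool alone would give opposite changes in both comparisons, which are therefore not independent results. Nppa was 256 against 1858 FPKM (7.26-fold), Ankrd1 754 against 1688 (2.24-fold) and Myh7 25.04 against 330.4 (13.2-fold, uncertain by overlap), while Nppb was 568 against 576. Of 23 stress genes, 13 were at least 1.5-fold lower and 1 higher, with a median of -0.62 (percentile 0). Atrial markers were lower as well (median -0.57, percentile 0.02), including Pam, a peptide-amidating enzyme, at 156 against 382. Contractile genes had a median of -0.19 (percentile 4.38), and -0.21 (percentile 1.20) among genes with a mean FPKM of at least 5. Mybpc3, cardiac myosin binding protein C, was 907 against 1635.

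Several matricellular genes were lower in the same comparison, but the call on their list depends on the setting. Thbs4 was 1.75 against 9.44 FPKM (5.40-fold), Comp 2.17 against 10.04 (4.63-fold) and Ltbp2, a latent TGF-beta binding protein, 1.05 against 6.18 (5.88-fold). Of 35 members, 11 were at least 1.5-fold lower and 3 higher, with a median of -0.21 (percentile 1.15). Among members without a copy the median was -0.10 (percentile 27.37), and -0.14 (percentile 2.15) when these were also centred by length and exon number. Epicardial and mesothelial markers were lower here (-2.11, percentile 0.05), a call that ended with no filter and among genes with a mean FPKM of at least 5. Collagen genes had a median of -0.02 (percentile 62.8), and 0.13 (percentile 97.70) among members without a copy after centring. Serpinh1 was 143 against 59.6, and Col14a1, a fibril-associated collagen, was 6.01 against 10.6.

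Glycolytic and metabolic HIF targets had a median of 0.06 (percentile 90.4) over all members and -0.03 (percentile 73.6) among those without a copy, so this list was not apart between these libraries. Gapdh was 2110 against 4.98 FPKM and Pgk1 282 against 31.6, both with copies and uncertain. Angiogenic genes had a median of 0.28 (percentile 99.97), with 6 of 30 at least 1.5-fold higher and 4 lower, which ended after centring the members without a copy (0.075, percentile 86.21). Aplnr was 25.8 against 3.77 (6.85-fold), Apln 7.93 against 2.35 (3.37-fold) and Calcrl 8.53 against 27.2 (3.19-fold lower). Endothelial markers had a median of 0.12 (percentile 98.2), with Vwf at 17.8 against 89.2 and Aqp1 at 196 against 49.4. Arterial genes had 0.11 (percentile 88.2, and 99.05 among members without a copy after centring), with Jag1, a Notch ligand, at 3.45 against 6.56. Venous and lymphatic genes had 0.24 (percentile 95.3, and 97.56 among genes with a mean FPKM of at least 5), with Nrp2, a receptor for lymphatic growth factors, at 12.7 against 7.68. Smooth muscle and pericyte markers (0.18, percentile 98.6), fibroblast markers (0.29, percentile 99.80) and macrophage markers (0.47, percentile 100) stood apart on the higher side. Vtn, vitronectin, was 23.9 against 8.29, Cd248, a stromal surface protein, 7.79 against 3.37, and C1qa, a complement component made by macrophages, 60.4 against 28.5.

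Of 11999 genes kept, 517 were at least 2-fold higher and 489 lower, again dividing by gene class. Of 272 pseudogenes, 14 were higher and 207 lower, and of 1668 coding genes with a copy, 357 were higher and 37 lower. Of 9488 coding genes without a copy, 111 were higher and 193 lower. Rescaling without the most abundant genes moved the median of all genes by -0.10. The authors' deposited table held 78 higher and 7 lower genes at a q-value of at most 0.05, of which 77 higher genes were coding genes with a copy. The authors' deposited table gave 8 coding genes without a copy, Aqp1 higher (q = 0.0112) and 7 lower. The lower genes were Myh7, Bdh1 (10.1-fold), Nppa (each q = 0.0112), Acer2, an alkaline ceramidase (7.58-fold, q = 0.0301), Myot (q = 0.0301), Cyfip2 (q = 0.0301) and Fmo2, a flavin monooxygenase (4.89-fold, q = 0.0387).

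For genes at least 2-fold apart between Egln1_Tie2Cre and floxed, the library labelled Egln1_Hif2a_Tie2Cre more often lay nearer the floxed value than the Egln1_Tie2Cre value. Of 340 such genes higher in Egln1_Tie2Cre and listed for the third library, 295 (86.8%, exact 95% interval 82.7 to 90.2) were nearer floxed, with a median position of 0.04. Of 459 lower genes, 424 (92.4%, interval 89.6 to 94.6) were nearer floxed, with a median position of -0.07. These numbers leave out 131 of 471 higher genes but only 1 of 460 lower genes, which the table of the third library with floxed does not list. Its table with Egln1_Tie2Cre lists 73 of the 131, and with its values the share was 89.1% of 413 higher genes (interval 85.7 to 91.9). Among coding genes without a copy the shares were 81.3% of 171 higher genes (interval 74.6 to 86.8) and 78.2% of 78 lower genes (interval 67.4 to 86.8), with median positions of 0.13 and 0.17. Nppa, Ankrd1, Thbs4, Comp and Aplnr lay nearer floxed in this sense, whereas Nppb and Slc16a3 did not. Because the genes were chosen on the other libraries, noise alone would put the median position at 0.5 if all libraries were equally noisy. If the spread of each library among genes without a copy were normal noise alone, the median position would be 0.31 and 78.9% of such genes would lie nearer floxed (robust SD 0.297 for Egln1_Tie2Cre, 0.2 for floxed and 0.198 for the library labelled Egln1_Hif2a_Tie2Cre). Both intervals of genes without a copy include that share. With 1 pool per genotype, however, the spread also holds any genotype change particular to a library, so this comparison neither shows nor excludes a return towards floxed. The shares over all genes include genes with copies and pseudogenes, whose values are uncertain.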

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

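The alternatives restricted to coding genes without a copy, with or without centring by length and exon number, were chosen only after the results were seen, and the others were fixed beforehand. No paired analysis was possible because each genotype has 1 pooled library. Of 802 list medians recomputed under alternatives, 746 kept their side of the percentile limits, 30 newly stood apart and 26 no longer did. Of called lists, 0 turned to the other side of the median of their random lists, while 31 lists without a call did. Part of this stability is built in. Median centring moves a list and its random lists alike, rescaling nearly does, and the other table repeats nearly all FPKM. These settings kept 103, 104 and 102 calls of 104 each. Of 60 recomputed counts of genes, 28 stayed within 1.5 times the main count and 32 moved further. Of 5693 recomputed values of named genes, 145 moved, all with the pseudocount of 0.1, and 0 reversed. Most settings could not move them. The filters, the restriction to genes without a copy and the other table only drop genes or reread nearly identical FPKM. Median centring shifts all ratios of a comparison by the same small amount. Unless a value's own construction shows it (fewer genes kept, a lower or stricter threshold), the cause was not tested. Depth is unknown, so how far it limits genes of low FPKM could not be computed.

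With a pseudocount of 0.1, Egln1_Hif2a_Tie2Cre over floxed had 153 genes higher and 153 lower, and 81.0% of higher and 89.4% of lower genes lay nearer floxed in the position measure. With no filter, the matricellular median of Egln1_Hif2a_Tie2Cre over Egln1_Tie2Cre was -0.11 and no longer apart. With a mean FPKM of at least 5, Egln1_Tie2Cre over floxed had 312 genes higher, Egln1_Hif2a_Tie2Cre over Egln1_Tie2Cre had 320 lower, and Egln1_Hif2a_Tie2Cre over floxed had 34 higher and 31 lower. The same filter brought the angiogenic list (0.29) for Egln1_Tie2Cre over floxed and the contractile list (-0.21) for Egln1_Hif2a_Tie2Cre over Egln1_Tie2Cre apart. It ended the matricellular call for Egln1_Hif2a_Tie2Cre over Egln1_Tie2Cre (-0.21) and over floxed (0.15), and put 96.1% of lower genes nearer floxed. Rescaling without the 20 most abundant genes gave 41 higher and 106 lower for Egln1_Hif2a_Tie2Cre over floxed, and 90.9% and 88.4% nearer floxed.

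Among coding genes without a copy, counts higher and lower were 185 and 78 for Egln1_Tie2Cre over floxed, 111 and 193 for Egln1_Hif2a_Tie2Cre over Egln1_Tie2Cre, and 35 and 30 for Egln1_Hif2a_Tie2Cre over floxed. The glycolytic list came apart for Egln1_Tie2Cre over floxed (0.33), the matricellular list of Egln1_Hif2a_Tie2Cre over Egln1_Tie2Cre no longer did (-0.10), and 81.3% and 78.2% of genes lay nearer floxed, where 78.9% would if the spread of these genes were noise alone. Centring these genes by length and exon number gave 172 and 83, 115 and 174, and 34 and 29 in the same order. For Egln1_Tie2Cre over floxed the glycolytic (0.26) and contractile (-0.085) lists then stood apart. For Egln1_Hif2a_Tie2Cre over Egln1_Tie2Cre the collagens (0.13) did and the angiogenic list (0.075) did not, and for Egln1_Hif2a_Tie2Cre over floxed the stress list (0.15) did. At 1.5-fold the counts were 1133 and 1046, 1160 and 1157, and 525 and 390 in the same order, with 71.1% (interval 68.2 to 73.9) and 80.5% (77.9 to 82.8) nearer floxed. These shares are over all genes, and the value of 70.2% from noise alone was computed for genes without a copy, so it is not their chance value. Adding the authors' q-value of at most 0.05 to the 2-fold threshold left 8 and 61, 78 and 7, and 1 and 1.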

Other observations

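Of the tests weighed below, the tests of nuclear respiratory genes, of length and exon number, and of atrial tissue were chosen only after the results were seen, and the tests of summed gene families were fixed before their results. Interferon response genes were lower in the Egln1_Tie2Cre library, with all 23 measured members below the floxed library, 12 of them at least 1.5-fold, and a median of -0.61 (percentile 0). Ifi44, an interferon-induced gene, was 0.605 against 2.63 FPKM, and Ifit3, another interferon-induced gene that has a copy and is uncertain, was 3.34 against 12.4. The same list was higher in the library labelled Egln1_Hif2a_Tie2Cre than in Egln1_Tie2Cre (0.65, percentile 100) and was not apart from floxed (-0.06, percentile 31.5). Macrophage markers, given above, took the same directions in Egln1_Tie2Cre over floxed (-0.27) and in Egln1_Hif2a_Tie2Cre over Egln1_Tie2Cre (0.47). In Egln1_Hif2a_Tie2Cre over floxed their median was positive (0.13), opposite in sign to the interferon median. Neither list stood apart there, though the macrophage list did among genes with a mean FPKM of at least 5, as given above. For these and other lists, opposite medians in the comparisons that share the single Egln1_Tie2Cre pool could come from that pool alone. Unfolded protein and amino acid stress genes were higher than floxed in both other libraries, at 0.34 (percentile 99.90) and 0.38 (percentile 99.99), and did not stand apart between these (-0.02, percentile 46.6). Atf3, a stress-induced transcription factor, was 1.66, 7.60 and 5.63 in the floxed, Egln1_Tie2Cre and Egln1_Hif2a_Tie2Cre libraries. Gdf15, a stress-induced cytokine, was 0.668, 4.99 and 1.11. Fatty acid uptake and oxidation genes were lower in Egln1_Tie2Cre (-0.25, percentile 0.02, and -0.24, percentile 0, without copies). They were higher in Egln1_Hif2a_Tie2Cre than in Egln1_Tie2Cre (0.19, percentile 99.1) and lower than floxed (-0.10, percentile 0.12), where the call ended after centring (percentile 7.25). Ppara, the fatty acid-sensing nuclear receptor, was 6.75 against 13.7 in the last comparison. Proliferation genes were lower in Egln1_Tie2Cre (-0.53, percentile 0) and in Egln1_Hif2a_Tie2Cre (-0.22, percentile 0.86) than in floxed. They were higher between these (0.33, percentile 98.9, but 78.6 without copies). Top2a, a topoisomerase of dividing cells, was 4.15, 0.357 and 1.78.

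Epicardial and mesothelial markers were higher in the Egln1_Tie2Cre library (1.78, percentile 99.99, 5 members) and lower in Egln1_Hif2a_Tie2Cre than in it (-2.11, percentile 0.05), with no call against floxed (-0.26, percentile 9.63). Both calls ended among genes with a mean FPKM of at least 5, and the second also with no filter. Wt1, an epicardial transcription factor, was 2.25, 10.2 and 1.60 in the 3 libraries, and Krt18, a simple-epithelium keratin, was 0.255, 7.21 and 0.204. Neutrophil and mast cell markers had 3, 3 and 4 measured members, led by S100a8 and S100a9, with medians of 3.74 (percentile 99.98), -2.17 (percentile 0.10) and 0.80 (percentile 99.98, but 89.6 with no filter) in the order of comparisons used for the targeted genes. Lymphocyte markers had fewer than 3 measured members in each comparison. Endothelial activation and cytokine genes were at 0.30 (percentile 99.91), 0.15 (88.3) and 0.09 (91.5, but 98.37 with no filter and 99.94 at a mean FPKM of at least 5), with Icam1, a leukocyte adhesion molecule, at 9.69 in Egln1_Tie2Cre against 3.60 in floxed. Antigen presentation genes were at -0.08 (13.6), 0.39 (99.79) and 0.22 (95.7). The first stood apart after centring members without a copy (-0.23, percentile 0.68), and the last among members without a copy (97.92) but not after centring (90.97). Erythroid genes were at 0.02 (41.8), -0.46 (0.21) and -0.35 (0.08, but 6.51 without copies and 0.63 after centring these). In the second comparison their members were split, with 4 higher and 6 lower. Platelet genes were at 0.13 (75.2), 0.10 (63.4) and -0.01 (48.5). Immediate early genes were at 0.10 (74.5), 0.13 (94.8) and 0.37 (100). The first stood apart after centring members without a copy (0.36, percentile 100), and the second among members without a copy (97.67) but not after centring (36.64). Their example is Klf4, a shear-responsive transcription factor, with 21.5 in Egln1_Hif2a_Tie2Cre against 9.78 in floxed. Clock genes were at 0.04 (44.2), -0.25 (2.62, but 0.51 after centring members without a copy) and -0.24 (0.10), with Arntl, the core clock activator, at 1.63 against 0.433 and Cry2, a clock repressor, at 8.90 against 14.2 in the last comparison. Iron genes were at -0.06 (16.3), -0.06 (44.4) and -0.04 (25.8). Nuclear oxidative phosphorylation genes were at 0.31 (97.6, a call that ended under 7 alternatives), 0.00 (63.2) and 0.37 (91.0). The last stood apart among members without a copy (0.33, percentile 99.61) and after centring these (0.14, percentile 97.94). Mitochondrially encoded genes were at -0.64 (0.03), 1.07 (99.98) and 0.47 (96.3, but 97.96 with no filter), and ribosomal protein genes, besides their value above, at 4.04 (100) and 0.52 (99.99). Nearly all ribosomal members have a copy and are uncertain, and no version of that list was centred by length and exon number. Atrial markers were at 0.18 (90.4, but 99.21 at a mean FPKM of at least 5) for Egln1_Hif2a_Tie2Cre over floxed. Conduction and valve genes were at 0.21 (87.6), -0.18 (19.6) and 0.15 (85.7), adipocyte markers at -0.18 (13.3), 0.03 (60.0) and -0.21 (4.61), and Schwann cell markers at -0.21 (19.1), 0.12 (67.6) and -0.05 (41.3). Lung, liver and skeletal muscle markers had fewer than 3 measured members in the first comparison and were at 0.07 (55.8) and 0.31 (86.0, but 98.05 with no filter) in the others. Sex-linked genes were at -0.31 (4.97), -0.55 (1.90) and -0.83 (0), the last calls ending with a mean FPKM of at least 5 (2.84 and 20.9) and the second also after centring members without a copy (-0.39, percentile 3.23). Xist, transcribed from the inactive X chromosome of females, had 16.5, 18.9 and 30.2 FPKM, and the Y-linked gene Ddx3y had 11.4, 8.74 and 5.59, but Eif2s3y, also Y-linked, had 19.2, 27.0 and 17.3. The labels do not give the sex of the pooled mice, and every pool holds transcripts of both sexes at different levels. A different mix of sexes between pools is confounded with genotype here.

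In the Egln1_Tie2Cre library against floxed, 334 of 1677 coding genes with a copy were at least 2-fold lower, and most pseudogenes were higher. Lower mRNA of nuclear respiratory genes is argued against for the 31 oxidative phosphorylation genes without a copy, which had a median of 0.31 (quartiles 0.15 to 0.47). The 8 members with a copy had a median of -0.35, and the 2 family sums available for them had a median of -0.94. These members are not covered by that test and stay open. The same holds for the mitochondrially encoded genes, of which 11 of 11 were lower (-0.64, percentile 0.03). Reads of a gene placed on its copies may account for part of the low genes and high pseudogenes. Of 161 low genes with a listed pseudogene copy, 139 (86.3%) had a copy at least 2-fold higher, against 43 of 81 other such genes (53.1%). Yet 192 of all 260 pseudogenes (73.8%) were that high and the number of copies was not matched. The difference in shares therefore does not show reads moving between a gene and its own copies. The sum of each low gene with its copies had a median of -1.13 against -2.98 for the gene alone. Adding mostly high pseudogenes brings such a move in any case. By the bound of -1 set beforehand, that median counts against this explanation. The margin is smaller than the spread between families (quartiles -1.85 to -0.68), which is not an error of the median and was not part of that rule. Pseudogenes that the deposited table does not list are missing from the sums, so the result is left undecided. Lower ribosomal protein mRNA cannot be told apart from reads placed on copies either, because the family sums of 19 members had a median of -0.97 with quartiles of -2.20 to -0.37. The 1 measured ribosomal member without a copy was higher (0.78), but a single gene cannot decide between them. A difference in how this library was aligned and a difference between genotypes both stay open, untested.

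As a list, HIF target genes without a copy were higher than floxed in both the Egln1_Tie2Cre library and the library labelled Egln1_Hif2a_Tie2Cre. Of 20 members, 4 were lower in the former, Egln3 among them, and 5 in the latter. Log2 ratios of genes without a copy also varied with transcript length, with Spearman's rho across genes (which are not independent) of -0.40 for Egln1_Hif2a_Tie2Cre and -0.19 for Egln1_Tie2Cre over floxed. After centring by length and exon number the list stayed at percentile 100 and 99.63 in these comparisons, which argues against that trend as the whole cause. Both comparisons share the floxed library, so a low value of these genes in that single pool would give the same pattern and was not tested. An effect of Egln1 deletion stays open as a hypothesis that 1 pool per genotype cannot test, and Egln1 was not lower in the library labelled Egln1_Hif2a_Tie2Cre.

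Natriuretic peptide and other stress genes were higher in the Egln1_Tie2Cre library. Shared reads or length and exon number are argued against, since the stress list stayed at percentile 100 after both corrections. Atrial tissue in that pool remains possible, because the 10 atrial markers other than Nppa had a median of 0.70 at percentile 99.99, 5 of them at least 2-fold higher. These 10 genes ranged from -0.52 to 1.46 and 2 were lower, and a stressed ventricle may raise some of them too, so this test does not separate the explanations. The genotype stays open as well, untested with 1 pool each. Whether atrial tissue also adds to the matricellular genes, which were higher in the same library, was not tested.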
